A study of Mus musculus with 2 samples.

How the data were processed

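PolyA-selected RNA from the small intestine of adult male B6NCrl mice, aged 8 weeks, was sequenced in 2 libraries, biological replicates 1 and 2 per the labels. The labels describe each sample as coming from a single mouse but give both the same donor identifier, so whether 2 animals were used is not settled, and the spread between the libraries may be technical. There was 1 group and no contrast.

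Per the deposited descriptions, the tables were made on mm10 with GENCODE M4 annotation from alignments to the transcriptome. The aligner, the quantification program, their versions and the strand setting are not given in the sources used here. Per the file headers, each gene table holds an expected count, a TPM (transcript abundance relative to a fixed total) and an FPKM value per row, with posterior mean estimates and their spread beside them. Per the file headers, the transcript tables add each transcript's percent of its gene (isoform percent). TPM and FPKM were normalized by the authors for transcript length and library total, and the posterior standard deviations of the counts were deposited on the scale of expected counts. The difference between length and effective length corresponds to reads of 36 bases.

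Each gene table had 69691 rows: 43346 mouse gene rows, 26248 transfer RNA rows, 96 ERCC spike-in rows and 1 phiX174 row. The last 3 kinds name no mouse gene of the comparisons and were left out of them, although the deposited TPM totals include them. The phiX174 row held 83.3% of all expected counts in replicate 1 and 79.3% in replicate 2. Transfer RNA rows held 0.0628% and 0.0174%, and ERCC rows held 0 in both libraries, which allows up to 3 counts. Mouse gene rows held 24329 and 32131 expected counts. Gene symbols and positions came from GENCODE vM21 (mm10), matched on the identifier without its version for 42462 gene rows.

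At this depth, 1 read in a transcript of 2000 bases gave 9.67 TPM in replicate 1 and 10.3 in replicate 2, so a mean TPM of 1 meant about any read. Posterior mean TPM was 2.3 and 2.28 at the median in genes without a read. Levels are means ± SD of deposited TPM (n = 2). Intervals are exact 95% Clopper-Pearson intervals, for ratios conditional on the sum of the counts, after rounding expected counts to whole numbers. Reads carried no molecular identifiers, so intervals and floors (3 counts for a count of 0) cover counting error only. No test across animals was possible with 1 library on each side of the comparison, and no p-value is given.

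Before the data were examined, 7 results, 46 gene lists with 518 memberships (491 of 492 distinct genes matched) and the rule for named genes were fixed. The named genes are the 20 with the highest mean TPM, up to 4 members of each list by mean TPM (2 for other tissues), the 12 higher in each library with the largest log2((TPM + 1)/(TPM + 1)) difference at a mean TPM of at least 5, up to 4 leading members of each list standing apart, and the isoform genes at a mean TPM of at least 5. Others were chosen after their values were seen. Differences are coded replicate 2 minus replicate 1, with a pseudocount of 1 and a mean TPM of at least 1. A list with at least 4 such members stood apart when the median of its differences lay below percentile 2.5 or above 97.5 among 10000 random lists matched on mean expression in 20 bins; about 5% of lists do so by chance. Counting error alone was simulated with 20 Poisson pairs of libraries, with the mean of each gene's observed shares as its true share in both libraries.

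Because the counts were so low, comparisons on expected counts were added after the data were seen. Their denominator was the count on core genes, 11111 in replicate 1 and 26904 in replicate 2. Core genes are nuclear genes other than 14 satellite-like genes, picked after the data were seen, and mitochondria-like pseudogenes sharing at least 20% of their 36-base words with mitochondrial transcripts. Among the 14, Gm10680 overlaps Apoa4 on the opposite strand, and their counts in replicate 1 (39.3 and 76.7) sum to 116, so reads of the 2 cannot be told apart and its place in the set is doubtful; counted as a core gene it moved the core counts of replicate 1 to 11150. The same sums were also taken over nuclear genes without the satellite-like genes and over all gene rows. Gene rows without annotation were counted as nuclear, among them an identifier without a symbol (755 and 0 counts) whose chromosome is not known here. Gm42418 (415 and 4277 counts) was kept as a core gene as well. Core shares without these rows were not computed, so core ratios with an interval that ends near 1 are uncertain. Alternatives were other pseudocounts, filters and units, edgeR TMM factors, DESeq2 size factors (both on expected counts rounded to whole numbers), length matching, another background and each library alone.

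The procedures were tested on simulated counts for the 43346 gene rows, with 200 genes of at least 20 counts changed between replicate 2 and replicate 1. The 2-fold threshold in TPM found 58.9% of genes changed 2-fold, 91.7% of those changed 4-fold and 98.4% of those changed 8-fold. It also passed 13.2% of the few genes with at least 20 counts that were left unchanged. With no gene changed, it passed a median of 3475 of 5518.5 detected genes in TPM, and 10 of 211.5 genes with at least 20 counts on shares of the gene counts. The exact intervals held the true ratio for 96.6% of the 200 changed genes. With no list changed, 2.26% of lists stood apart, and an enterocyte list of 13 genes raised 4-fold was found in 100% of 20 runs. Raising lists with fewer counts was not tried. Over 211 genes with at least 20 counts, the libraries differed far beyond sampling noise (chi-square per degree of freedom 121), so they were kept as 2 libraries. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, bedtools 2.31.1, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0 were used.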

Results

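RNA of the adult mouse small intestine was measured by polyA-selected RNA sequencing in 2 libraries of 1 group. The gene tables held 146585 expected counts in replicate 1 and 155255 in replicate 2, of which 24329 (16.6%, exact 95% interval 16.4 to 16.8) and 32131 (20.7%, 20.5 to 20.9) lay on mouse genes. A read was counted for 3273 genes in replicate 1, for 5542 in replicate 2 and for 1721 in both. At a mean TPM of at least 1, 7042 genes were detected, but only 1345 had at least 5 counts over both libraries. Values of single genes below about 20 counts therefore carry wide counting error, and a gene listed at 0 was not shown to be absent. Gapdh was listed at 0 in both libraries.

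The 2 libraries held the transcripts of absorptive intestinal epithelium at their clearest. All 13 enterocyte genes had at least 5 counts, with 409 counts in replicate 1 and 1237 in replicate 2. Fabp2, an intestinal fatty acid binding protein, had a mean of 2013 ± 853 TPM (SD, n = 2), and Apoa1, an apolipoprotein of secreted lipoproteins, had 1486 ± 1244 TPM. Anpep, a brush border aminopeptidase, had 1272 ± 1689 TPM, and Sis, the sucrase-isomaltase, had 755 ± 583 TPM. The lists of carbohydrate digestion (186 and 758 counts), peptide and amino acid uptake (75 and 710) and lipid absorption (295 and 445) had 9 of 11, 11 of 14 and 11 of 16 members with at least 5 counts. Among them, Aldob, the fructose-bisphosphate aldolase, had 19 and 125 counts, Mgam, the maltase-glucoamylase, 32 and 261, and Slc5a1, the sodium-glucose cotransporter, 15 and 77. Ace2, a carboxypeptidase, had 30 and 41 counts, and Slc15a1, the peptide transporter, 10 and 51. Apoa4 had 76.7 and 47 counts and overlaps Gm10680 (39.3 and 0) on the opposite strand, so its counts are uncertain; Fabp1 had 23 and 5.

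Secretory and defence genes were also present. The goblet cell list had 95 counts in replicate 1 and 226 in replicate 2, led by Zg16 (2564 ± 764 TPM) and the mucin Muc2 (403 ± 252 TPM). The Paneth cell list had 3 and 126 counts, of which Lyz1, a lysozyme, gave 2 and 87.9 and the defensin Defa17 0 and 13.6. Counts of defensins may be split among near-identical family members and are uncertain for each gene. The epithelial defence list had 29 and 248 counts, with the lectin Reg3b at 9 and 116 and Pigr, the polymeric immunoglobulin receptor, at 8 and 93. Reg3g (6 and 15 counts) and Reg3a (5 and 7) belong to a family of close paralogs too. Plasma cell genes had 44 and 248 counts, nearly all on the constant regions Igha (8 and 240) and Igkc (35 and 4).

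Other cell types had few counts. Enteroendocrine genes had 1 count in replicate 1 and 5 in replicate 2, tuft cell genes 1 and 0, stem cell genes 1 and 7, and proliferation genes 4 and 16. T cell and intraepithelial lymphocyte genes had 3 and 14 counts, led by Gzma with 2 and 9. B cell genes had 1 and 2 counts, macrophage and dendritic cell genes 2 and 5, and mast cell genes 0 in both. Smooth muscle genes had 3 and 90 counts, fibroblast genes 1 and 15, endothelial genes 0 and 3, enteric glia genes 6 and 1, and enteric neuron genes 0 in both. Of other tissues, erythroid, pancreatic acinar and stomach genes had 0 counts in both libraries. Adipocyte genes had 0 and 3 counts, hepatocyte genes 0 and 3, skeletal muscle genes 0 and 1, and colon genes 0 and 5, led by Car4 and Satb2. A count of 0 allows up to 3 counts, so the lists at 0 in both libraries were not detected at this depth, which does not show that they were absent.

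The lists for both ends of the small intestine had counts. The proximal list had 22 counts in replicate 1 and 31 in replicate 2, of which Lct, the lactase, gave 18 and 25. Without Lct, which is in the enterocyte list too, the proximal list had 4 and 6. The distal list had 8 and 62 counts, with the bile acid binding protein Fabp6 at 0 and 10, Slc51a at 2 and 20 and Cubn at 5 and 32. Of regulatory and metabolic lists, intestinal transcription factors had 8 and 70 counts, led by Hnf4a with 2 and 48. Epithelial junction genes had 22 and 135 counts, with Epcam at 2 and 70. Xenobiotic metabolism genes had 62 and 118, with Cyp3a13 at 30 and 22 and Cyp3a25, which has close paralogs, at 0 and 20. Cholesterol synthesis genes had 11 and 77 counts, and fatty acid oxidation genes 6 and 18. Circadian clock genes had 6 and 24 counts, immediate early genes 14 and 22, heat shock genes 15 and 10, endoplasmic reticulum stress genes 2 and 20, MHC class II genes 2 and 19, and interferon-stimulated genes 4 and 15. The sex-linked list had 3 and 5 counts, with Ddx3y at 2 and 3 and Xist at 0. Over all lists, 274 genes were detected at a mean TPM of at least 1, and 121 had at least 5 counts. In replicate 1 alone, 151 were detected.

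The most abundant rows were not typical of nuclear messenger RNA. The 20 genes with the highest mean TPM held 38.5% of TPM in replicate 1 and 17.2% in replicate 2 (27.8 ± 15.0%, SD, n = 2). The deposited TPM total includes the phiX174 and transfer RNA rows; over gene rows alone the shares were 72.6% and 33.2%. Of these, 10 were genes of the mitochondrial genome, led by mt-Co2 with 2744 and 0 counts, mt-Atp6 with 1549 and 198, mt-Rnr2 with 780 and 1571, and mt-Co1 with 228 and 1401. Gm28437 and Gm28661, pseudogenes on chromosome 1 at 24613189 to 24613971 and 24614885 to 24615565 (mm10), had 5003 and 0 counts and 0 and 495 counts, and share 100% of their 36-base words with mitochondrial transcripts. Reads of such copies cannot be assigned with certainty, so each is uncertain. Gm42418 on chromosome 17 (39846958 to 39848788) had 415 and 4277 counts. Gm10801 and Gm10800, a pair of satellite-like genes on chromosome 2 from 98662237 to 98667301, had 731 and 1.08 counts and 532 and 4.92 counts. The list also held Gm15564, Prr15, Akr1a1, Actg1 and an identifier without a symbol in the annotation used here.

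**Figure D1:**
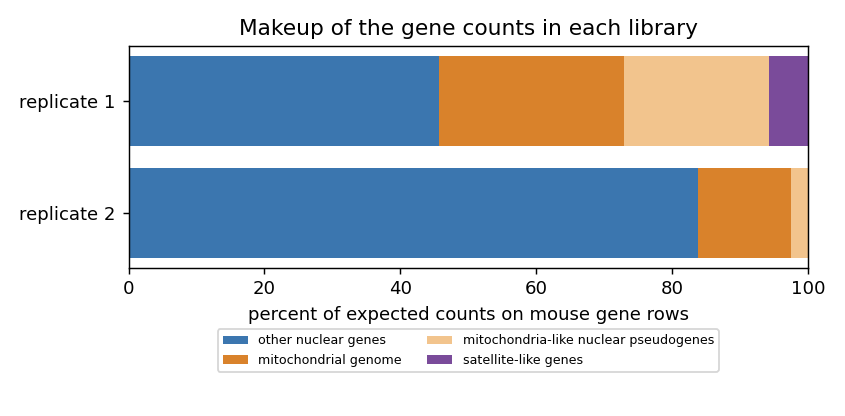
Makeup of the expected counts on mouse gene rows, in percent (x axis), for each library (y axis, 1 bar per library). Core genes, drawn as other nuclear genes and including gene rows without annotation, held 45.7% of the bar in replicate 1 and 83.7% in replicate 2.

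The libraries differed in this makeup. Genes of the mitochondrial genome and the pseudogenes that resemble them held 48.5% of the gene counts in replicate 1 (exact 95% interval 47.9 to 49.1) and 16.2% in replicate 2 (15.8 to 16.6). Satellite-like genes held 5.82% (5.53 to 6.12) and 0.0716% (0.0454 to 0.107). Of the control lists, mitochondrial-encoded genes had 5079 and 2549 counts, non-polyadenylated RNAs 3 and 0, and ribosomal protein genes 16 and 77, of which Rpl4 gave 0 and 59. Without mt-Co2 (2744 and 0 counts), the mitochondrial-encoded list had 2336 and 2549. Its share of all gene counts then had a ratio of replicate 2 to replicate 1 of 0.83 (0.78 to 0.87). In TPM, 9 of its 13 members were higher in replicate 2 and 4 in replicate 1. Much of the gap in mitochondrial share thus rested on mt-Co2 and on Gm28437 (5003 and 0 counts), whose reads cannot be assigned with certainty.

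Compared gene by gene, 6286 of the 7042 detected genes differed at least 2-fold in TPM, 4585 higher in replicate 2 and 1701 higher in replicate 1. By posterior mean TPM the number was 619, with 485 and 134. Counting error alone gave a median of 3475 genes over 20 simulated pairs (range 3407 to 3557), among a median of 5518.5 detected genes. The simulated pairs took the mean of each gene's observed shares as its true share, so genes without a read could not appear in them. They held fewer detected genes than the 7042 observed, so their values over all detected genes are rough baselines only. Among 211 genes with at least 20 counts, 176 differed at least 2-fold in their share of the gene counts, against a median of 10 (4 to 16) from counting error alone. Of the 176, 130 were higher in replicate 2 and 46 in replicate 1. Simulated pairs had the same makeup in both libraries, whereas observed ratios over all gene counts were 1.83 times those over core gene counts. The 176 therefore include this shift in makeup as well as differences of single genes. The median log2 ratio of TPM over 1721 genes with reads in both libraries was 1.04. Across detected genes, Pearson's r of log2(TPM + 1) was -0.20 and Spearman's rho of TPM was -0.24, against a simulated median r of 0.29; genes are not independent replicates. Requiring a read in either library admits genes seen in 1 library alone. Over the 1721 genes with reads in both, r was 0.57, and without a filter it was 0.37. No simulated r was taken for these 2 settings. The filter was not the only source of the low agreement. Over the 211 genes with at least 20 counts, r on log2 shares of the gene counts was -0.25, against a simulated median of 0.96 (0.95 to 0.97). Over the 183 core genes with at least 20 counts it was -0.20.

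On shares of the core gene counts, 183 core genes had at least 20 counts. The whole interval of the ratio lay above 2-fold higher in replicate 2 for 57 and above 2-fold higher in replicate 1 for 31. These numbers depend on the denominator, which was chosen after the data were seen: as shares of all gene counts, ratios of replicate 2 to replicate 1 are 1.83 times larger, and 85 and 22 genes passed. Among enterocyte genes, Anpep was 11.3-fold higher in replicate 2 (6.80 to 20.5), whereas Sis had a ratio of 1.09 (0.85 to 1.43) and Fabp2 of 0.72 (0.53 to 0.98). Over all gene counts, the ratio of Sis was 2.01 (1.55 to 2.62) and that of Fabp2 turned to 1.32 (0.97 to 1.80). Apoa4 was 3.97-fold higher in replicate 1 (2.72 to 5.83), and 5.96-fold (4.21 to 8.55) with the counts of Gm10680 added. The immunoglobulin genes went opposite ways, with Igha 12.4-fold higher in replicate 2 (6.19 to 29.0) and Igkc 21.2-fold higher in replicate 1 (7.58 to 82.1). Akr1a1, an aldehyde reductase, had 951 and 18 counts and was 128-fold higher in replicate 1 (80.5 to 217). Prr15 had 636 and 4 counts and was 385-fold higher in replicate 1 (150 to 1417). Lars2 had 17.0 and 638 counts and was 15.5-fold higher in replicate 2 (9.60 to 26.8). These examples were chosen after their values were seen, except where they lead a list or rank among the 20 most abundant.

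**Figure D2:**
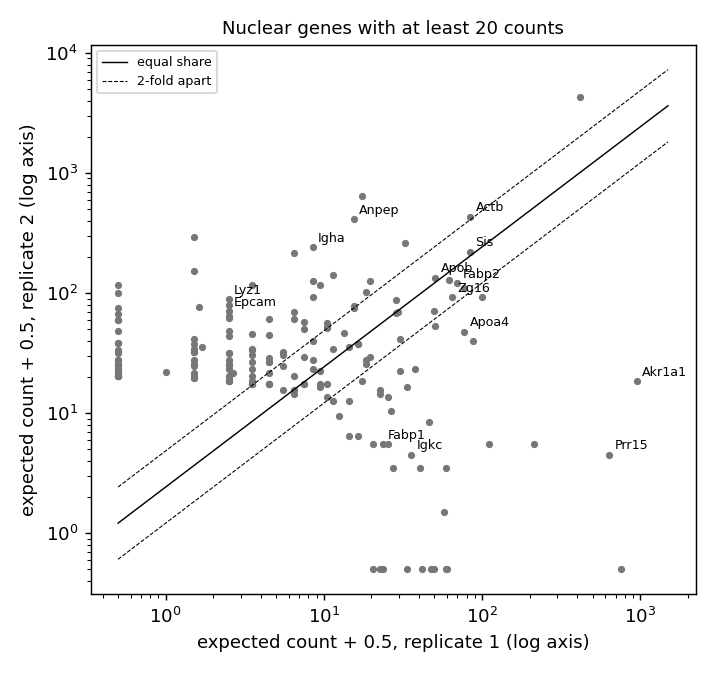
Expected counts plus 0.5 of 183 core genes with at least 20 counts, replicate 1 (x axis) against replicate 2 (y axis), both log axes. The solid line marks equal shares of the core gene counts and the dashed lines a 2-fold difference; Sis lies near the solid line, and Akr1a1 with 951 and 18 counts lies far below it.

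The largest log2 differences in TPM at a mean TPM of at least 5 belonged to genes listed at 0, or 0.01 TPM, in the other library. Higher in replicate 1 were Gm28437, mt-Co2, the identifier without a symbol (755 and 0 counts), mt-Nd4l (87 and 0), Gm29216 (140 and 0), mt-Te, Gm22973, Gm10680, Selenof (60 and 0), Rny1, Gm23617 and Gm21738. Higher in replicate 2 were Gm28661, Actg1 (0 and 116 counts), Gm28438, Gm2830 (0 and 75.0), Gm10925, mt-Tn, Gm13194, Gm24245, Gm24270, Gm23935, Mir6236 and Gm15312. Against the floor of 3 counts, Selenof, a selenoprotein, was at least 48.4-fold higher in replicate 1 on shares of core gene counts and 26.4-fold on shares of all gene counts. Actg1, the cytoplasmic gamma-actin, was at least 16.0-fold and 29.3-fold higher in replicate 2. The exact lower 95% bounds, which include the error of the other count, were 38.2 and 20.8 for Selenof and 12.8 and 23.4 for Actg1. Several of the others rested on fewer than 10 counts.

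Of 30 gene lists with at least 4 detected members, 2 stood apart between the libraries. By the percentile limits about 5% do so by chance, and 2.26% did in the simulation with no list changed. Smooth muscle genes were higher in replicate 2, with a median log2 difference of 5.47 over 10 members (percentile 98.2) and all 10 members higher in replicate 2. With 3 counts in replicate 1, the size depends on the pseudocount: it was 8.76 with 0.1 and 3.37 with 5. Tpm2 (0 and 4 counts), Acta2 (0 and 21), Actg2 (0 and 6) and Myl9 (0 and 4) are contractile genes. Paneth cell genes, with 3 counts in replicate 1, were higher in replicate 2 as well. Their median was 6.31 over 9 members (percentile 98.2), but 9.61 with a pseudocount of 0.1 and 4.69 with 5. All 9 members were higher in replicate 2. Defa17, Defa24 (0 and 8.37 counts), Defa21 (0 and 2.75) and Lyz1 were among them. Counts of the defensins may be split among near-identical family members, so the 9 members are not independent. The random lists do not allow for this. Only 4 of the 9 had at least 5 counts, and without Lyz1 the list had 1 and 38 counts. For scale, 72.9% of all detected genes that differed at least 2-fold in TPM were higher in replicate 2. The Paneth cell list no longer stood apart with TMM factors (percentile 92.4), with DESeq2 size factors (92.3), at a mean TPM of at least 5 (96.8) or with matching on length (94.6).

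On summed counts, an approach added after the data were seen, 18 of 45 lists had an interval of the share ratio that excluded 1, and 13 did after the member with most counts was left out. Over all gene counts 19 did, 18 of them higher in replicate 2. On shares of the core gene counts, Paneth cell genes were 17.3-fold higher in replicate 2 (5.80 to 85.2) and smooth muscle genes 12.4-fold (4.11 to 61.2). Peptide and amino acid uptake genes were 3.91-fold higher (3.08 to 5.03) and 2.05-fold (1.55 to 2.75) without Anpep. Epithelial defence genes were 3.53-fold higher (2.40 to 5.38). Lipid absorption genes were 1.61-fold higher in replicate 1 (1.38 to 1.86). This direction depends on the scaling: the median log2 difference was -0.33 with TMM factors (percentile 1.44) and -0.50 with DESeq2 size factors (1.85), but 0.78 in TPM (6.5), and over all gene counts the ratio of replicate 2 to replicate 1 was 1.14 (0.98 to 1.33). Goblet cell genes had a ratio of 0.98 (0.77 to 1.26), but 1.79 (1.20 to 2.73) without Zg16 and 1.80 (1.41 to 2.31) over all gene counts, and all 8 detected members were higher in replicate 2 in TPM. Enterocyte genes were 1.25-fold higher in replicate 2 (1.12 to 1.40), but without Anpep the ratio was 0.86 (0.77 to 0.98). Over all gene counts it was 1.59 (1.40 to 1.79) without Anpep. In TPM 10 of 13 members were higher in replicate 2, but the median log2 difference of 1.25 lay at percentile 13.4 of matched random lists. The median of those random lists was 2.86, so the enterocyte list was less shifted toward replicate 2 than most of them. Plasma cell genes were 2.33-fold higher in replicate 2 (1.68 to 3.29), and 0.0918 (0.0368 to 0.201) without Igha.

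**Figure D3:**
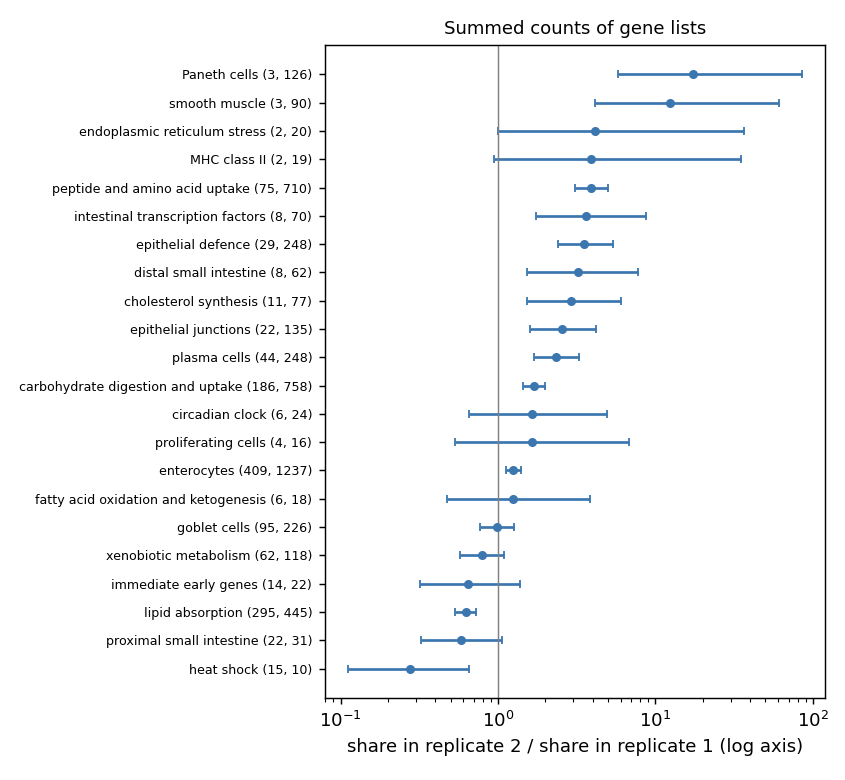
Ratio of the share of core gene counts in replicate 2 to that in replicate 1 (x axis, log axis) for 22 cell type, region and pathway lists with at least 20 summed counts and a count in both libraries (y axis, counts in brackets). Points are ratios and bars exact 95% intervals for counting error only; 12 lists lie wholly above 1 and 2, lipid absorption and heat shock, wholly below it. Over all gene counts neither of these 2 intervals excludes 1.

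The transcript tables allowed the leading isoform to be compared. Of 1186 genes at a mean TPM of at least 5 with several transcripts and reads in both libraries, 440 (37.1%, 34.3 to 39.9) had the same leading isoform, where 1 over the number of transcripts averaged 23.1%. By posterior mean isoform share it was 768 (64.8%, 62.0 to 67.5). Among 33 genes with at least 10 counts in each library it was 17 (51.5%, 33.5 to 69.2). Of the isoform genes, Vil1, the microvillus protein villin, had Vil1-201 in both libraries (6 and 69 counts), Hnf4a had Hnf4a-201 (2 and 48), and Mylk had Mylk-201 (2 and 27). Khk (7 and 17 counts) and Cdc42 (2 and 6) also kept their leading transcript, and Pkm was tied at 50% between its 2 transcripts. Ctnnd1 (4 and 21 counts) and Cdh1 (2 and 18) had different leading isoforms. Myl6 and Epcam have 1 transcript in the tables, and Tpm1, Tpm2, Fn1, Cald1 and Flna had no read in replicate 1. Vil1 overlaps Usp37 on the opposite strand, and the strand setting of the counting is not given in the sources used here.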

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

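The tests of signal file size and of reads shared between copies were chosen after the results were seen, as was the count of reads split between opposite-strand genes. Rows outside the comparisons held signal: phiX174, a bacteriophage genome used as a sequencing control, took 83.34% of all expected counts in replicate 1 and 79.29% in replicate 2. Transfer RNA rows held 92 and 26.98 expected counts, above the 3 that a count of 0 allows.

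Few reads lay on genes in either library. Too few sequenced and aligned reads are argued against by the listed sizes of the signal files of uniquely aligned reads, which were 36.5 and 26.0 times the largest file that the counted reads alone would make. Counting on the strand opposite to the RNA is argued against as well: of 172 protein-coding genes with at least 20 counts, 12.8% overlapped an opposite-strand coding gene, against a median of 11.6% in 1000 length-matched random sets (central 95%, 7.0 to 16.9). Counting by strand would keep reads of opposite-strand genes apart, yet where 2 such overlapping genes both had fractional counts, these summed to a whole number for 10 of 12 pairs in replicate 1 and 17 of 18 in replicate 2, against a median of 1 and 1 when partners were shuffled. File sizes give no number of aligned reads, so whether the deposited counts were made from the same full alignments stays open. The cause of the few gene counts stays open too, and no biological explanation was tested.

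Satellite-like genes held 1415 counts in replicate 1 and 23 in replicate 2, an 81.3-fold higher share of gene counts in replicate 1 (53.9 to 129; 79.0 without Gm10680, which overlaps Apoa4). Genomic DNA in the replicate 1 library is a candidate explanation: 1659 olfactory and vomeronasal receptor genes held 16 counts in 14 genes in replicate 1 and 0 in replicate 2, with a lower 95% bound of 5.09 on the ratio of shares. The test rests on 16 counts. Their density over all gene rows would come to 554 counts, 4.99% of the core gene counts of replicate 1, so it would account for few of the gene reads. The design gives no biological contrast to set against it, and none was tested.

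Many reads in 1 library alone were seen for 88 annotated nuclear genes with at least 20 counts in 1 library and an observed share at least 10 times that in the other, 25 in replicate 1 and 63 in replicate 2. Of these, 44 had 0 counts in the other library, and the exact lower bound on the ratio of gene count shares reached 10-fold for 33 (17 in replicate 1 and 16 in replicate 2), such as Akr1a1, Prr15, Usp25 and Cep97. Simple tandem repeats are argued against, since 7.95% of the 88 genes held a 36-base repeat window, against a median of 11.9% in 1000 length-matched random sets (5.7 to 19.3). Sharing of reads between annotated copies is argued against for the 88 genes as a set, since the posterior standard deviation was 0% of the count at the median; it was at least 10% for 9 genes. Amplification duplicates and a difference between the samples stay open and were not tested.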

How the results depend on the processing

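The comparisons on counts were added after the data were seen. Depth was a limit: a mean TPM of 1 meant about any read. Genes differing at least 2-fold numbered 6286 and stayed within 1.5 times of that under 7 of 9 alternatives; there were 619 with posterior mean TPM and 176 among genes with at least 20 counts, where fewer genes were tested. Agreement across genes (r = -0.20) moved to -0.38 and -0.0085 with pseudocounts of 0.1 and 5, -0.30 at a mean TPM of at least 5, -0.14 with FPKM and -0.25 at 20 counts, and turned to 0.37 without a filter, which adds genes at 0 in both libraries. Genes detected ranged from 3257 to 5541 with 1 library alone, and were 1345 at 5 counts or more. List genes detected ranged from 151 to 253 with 1 library alone and were 121 at 5 counts or more. The share of the 20 most abundant genes was 17.2% to 38.5% with 1 library alone, 8.74% on expected counts, which phiX174 dominates, and 52.9% over gene rows alone. Lists standing apart numbered 1 at a mean TPM of at least 5, 1 with length matching, 18 on summed counts over core genes (13 higher in replicate 2, 5 in replicate 1), 17 with Gm10680 counted as a core gene (13 and 4; non-polyadenylated RNAs, 3 and 0 counts, lost theirs), 13 without the top member, 19 over nuclear genes without satellite-like genes (16 and 3) and 19 over all gene rows (18 and 1). The leading isoform was the same for 32.6% of genes at a mean TPM of at least 20. By posterior means it was the same for 64.8%, part of which may not come from reads. Except where stated, the cause was not tested. For single lists, 258 percentiles under alternatives kept their call, 4 lost it (all Paneth cells) and 3 gained one, lipid absorption under both scalings and ribosomal proteins against protein-coding genes. For the 24 genes named for the largest log2 differences, 119 differences under alternatives kept a 2-fold size. Only 1 did not (Gm10925, 0.52 by posterior means), and none changed direction. These genes were picked for their size and had 0 or 0.01 TPM in 1 library, so other pseudocounts or scalings could hardly change them. Other named genes were not part of this check. TMM factors moved the median log2 ratio by -0.88 and DESeq2 size factors by -1.04. No paired analysis was possible because there was 1 group.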

Other observations

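The genes and counts in this paragraph were chosen after the data were seen. Beyond the lists, other core genes had many counts. Selenop, a secreted selenoprotein, had 99 counts in replicate 1 and 92 in replicate 2 (962 ± 26.7 TPM, SD, n = 2). The sodium pump subunits Atp1a1 and Atp1b1 had 76 and 109 counts and 50.0 and 53 counts; Atp1b1 overlaps Nme7 (9.96 and 0) on the opposite strand and is uncertain. Krt20, a keratin of differentiated epithelium, had 11 and 141 counts, the membrane mucin Muc13 had 3 and 116, and Tspan8 had 2 and 64. The paralogs Clca4a (28.9 and 69.5) and Clca4b (49.1 and 70.5) are uncertain for each gene. The cytochrome Cyp4f14 had 0 and 100 counts. The ferritin gene Fth1 had 15 and 75 counts, and Usp25 had 1 and 291, Cux2 214 and 5 and Cep97 1 and 152.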
